A study of Homo sapiens with 9 samples.

How the data were processed

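Polyadenylated RNA was sequenced from 9 human xenograft tumors of the prostate cancer line 16D, which the labels describe as castration-resistant. Per the labels, the cells carried CAS9 and either a control gRNA (5 tumors) or a gRNA against OGDHL (4 tumors) and were grown in immune-deficient NSG mice. Libraries were stranded by dUTP and read as pairs of 50 bases on a NovaSeq X Plus, per the labels' protocols, and were demultiplexed with bcl2fastq 2.19.1.403. Alignment used STAR and the build GRCh38, per the submitters' processing notes. The STAR version, the quantifier, the annotation release, the strand setting of the counting and any removal of mouse reads were not given in the sources used here.

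The deposited count table held estimated counts per gene from the authors, not scaled for depth, for 35060 gene IDs, 25986 of them with a symbol. Between 42.6% and 46.1% of the values of a tumor were whole numbers. The 35 largest values were all round numbers, so those few were rounded before deposit. The deposited TPM table was made by the authors. In every tumor at least 99.3% of its values equalled the count divided by the gene's genomic span, introns included, after scaling, within a tolerance of 0.1%. Such TPM values understate genes with long introns, so they served only as an alternative. On log2(TPM + 1) the median difference between the genotypes was -0.32 over the 14774 tested genes with a mean TPM of at least 1, so a change of sign on that scale is not read as one of a single gene. Every row named a gene, and 59 rows were 0 in all tumors. A symbol used for more than 1 gene ID (58 symbols) was assigned to the ID with the most counts.

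Estimated counts were rounded to whole numbers. The totals ran from 54270300 to 85380091 per tumor, so that 3 counts, used as the floor of detection, made up 0.0351 to 0.0553 CPM. The floor covers counting error only, since reads were not marked with molecular identifiers. Genes were filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3 (minimum count 10), which kept 24855 genes and removed 10205. Libraries were scaled by TMM, and CPM values below are TMM-scaled. Differences were tested with edgeR's quasi-likelihood test with robust estimation, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change over the square root of its F statistic. The main comparison set 4 OGDHL gRNA tumors against 5 control tumors. A second fit with 3 groups used the construct names in the titles, OGDHL2930 (2 tumors) and OGDHL2 (2 tumors), each against the 5 controls and against each other. Tests were adjusted within each comparison.

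A total of 46 gene lists were fixed before the data were examined, among them metabolic pathways, prostate lineage genes and markers of 8 host cell types. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), and again with an estimated correlation, with the directional p of fry, and with an exact two-sided permutation test of the tumors' mean list scores. A list score is the mean log2 CPM of the list's tested members after centring each gene over the 9 tumors. Exact tests enumerated all 126 splits of 9 tumors into 5 and 4, so their smallest possible p was 0.00794. Members were also adjusted over the list alone. The genes named below were chosen by a rule set beforehand: 13 fixed genes, the 8 largest changes past the threshold per direction without overlap between groups and with a mean log2 CPM of at least 1, the 3 members of smallest p in each of the 10 lists of smallest camera p, and 5 genes for the contrast of constructs. The parts that need an adjusted p under 0.05 gave 0 genes. Other genes named are marked as chosen after their values were seen.

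The main and the OGDHL2930 comparison by edgeR were tested on simulated counts with 50 changed genes per fold size among 24855, and camera on 1 shifted list. The changed genes were drawn only from genes with a mean log2 CPM of at least 1, so recovery of genes below that level was not simulated. Recovery by the other comparisons and tools was not simulated. In the simulated main comparison 6% of genes changed by 1.5-fold, 38% of those changed by 2-fold, 92% of those changed by 4-fold and 96% of those changed by 8-fold were recovered, with 9 false calls among 125. In the simulated OGDHL2930 comparison 2%, 26%, 76% and 94% were recovered. A simulated shift of the glycolysis list by -0.5 on the log2 scale was recovered, and 0 other lists were called. Genes were simulated independently of each other. The simulation therefore does not test camera on genes that vary together, as members of the real lists did (estimated correlation 0.346 for glycolysis). No pair of libraries was a duplicate by a chi-square test of counts, since the closest pair differed by 61.6 per degree of freedom.

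Alternatives were DESeq2 1.42.0, limma voom, other scalings and filters, limma on log2(TPM + 1) and log2(TPM + 0.1), tests against a fold change of 1.5, subsets of the controls and leaving out each tumor. The titles also carry a token (1M, 100K or 10K) whose meaning the labels do not give. All 4 OGDHL gRNA tumors and 1 control carry 100K, 2 controls carry 1M and 2 carry 10K, so the token was an alternative covariate. That fit sets 1 control, tumor 3, against the 4 OGDHL gRNA tumors, and assumes that this lone tumor varies like the others. The titles of controls also carry letters of unstated meaning, VB in control tumor 3 and BW in the other 4, and the OGDHL gRNA titles carry none, so token and letters cannot be told apart in control tumor 3. Single suffixes in the titles, also unexplained, were not used here. Transcript length and GC came from GENCODE release 29, which matched 96.3% of the tested genes. Figures were drawn with matplotlib 3.10.9. The labels call the samples separate tumors but do not say whether they came from separate mice or separate pools of edited cells, so p-values measure the spread between these tumors.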

Results

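Transcript levels were measured by RNA-seq in 9 xenograft tumors of the human prostate cancer line 16D, 5 with a control gRNA (AAVS in their titles) and 4 with a gRNA against OGDHL. Total counts were 69476364, 72948223, 75363971, 82051650 and 84887177 in control tumors 1 to 5 and 79903849, 66223440, 85380091 and 54270300 in OGDHL gRNA tumors 1 to 4. Tumors 1 and 2 of the OGDHL gRNA group carry the construct name OGDHL2930 in their titles and tumors 3 and 4 carry OGDHL2. Values are TMM-scaled CPM, given as mean ± SD over 5 control and 4 OGDHL gRNA tumors, unless another unit is named. Log2 fold changes are OGDHL gRNA minus control.

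OGDHL itself (ENSG00000197444, chromosome 10, 49734641 to 49762380 on the minus strand, GRCh38), which encodes a relative of the oxoglutarate dehydrogenase subunit OGDH, was measured first as a check of the labels. Its level was 22.8, 25.4, 19.2, 17.1 and 13.4 CPM in the controls (19.6 ± 4.71) and 9.00, 18.2, 6.54 and 5.87 CPM in the OGDHL gRNA tumors (9.9 ± 5.69). The mean was thus 50.6% of control (95% confidence interval 30.3% to 84.4%), a log2 fold change of -0.98 (SE 0.334). All 4 OGDHL gRNA tumors lay below the control mean, but tumor 2 lay inside the control range. The exact two-sided permutation p was 0.0397, while the adjusted p of edgeR over all genes was 0.297. An edit that shifts the reading frame need not lower the transcript, so the level does not measure editing. The partners of the enzyme complex, OGDH (-0.07), DLST (-0.27) and DLD (-0.19), had edgeR adjusted p of 0.849, 0.492 and 0.496. Against control tumor 3 alone, whose DLD level (150 CPM) was far below the other controls, DLD had the opposite sign.

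**Figure D1:**
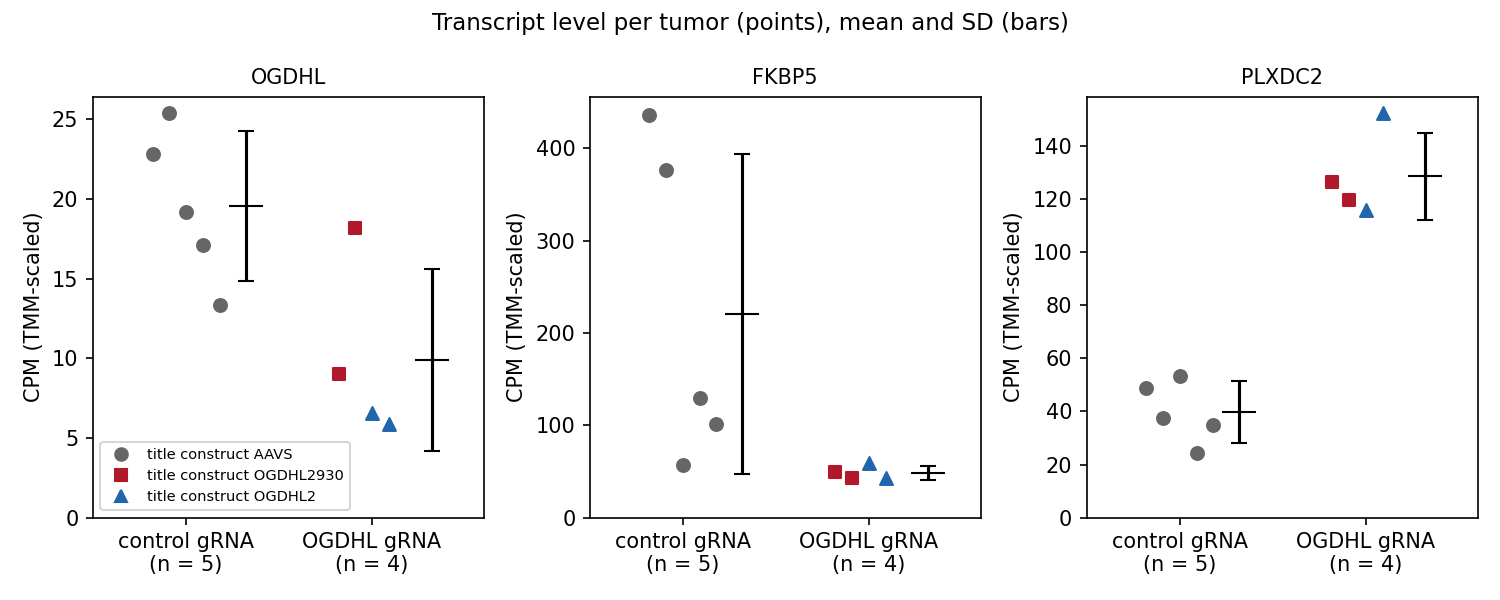
TMM-scaled CPM (y axis, from 0) of OGDHL, FKBP5 and PLXDC2 in each tumor (points, shaped by title construct), with the mean and SD of each group (bars) for 5 control and 4 OGDHL gRNA tumors (x axis). OGDHL in OGDHL gRNA tumor 2 (18.2 CPM) lies among the controls, FKBP5 is high in control tumors 1 and 2, and PLXDC2 does not overlap between the groups.

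The main comparison asked which transcripts differ between tumors with OGDHL gRNA and tumors with control gRNA. The smallest p by edgeR was that of PLXDC2 (ENSG00000120594), which encodes a membrane protein, at 129 ± 16.4 CPM in OGDHL gRNA tumors against 39.8 ± 11.6 in controls, a log2 fold change of 1.69 (SE 0.211). TPBG, which encodes the oncofetal antigen trophoblast glycoprotein, was at 5.07 ± 1.11 against 1.34 ± 0.593 CPM, and ELAPOR1 was at 12.1 ± 4.63 against 3.33 ± 1.13 CPM. CAMK2D, a calmodulin-dependent kinase, was at 31.9 ± 7.38 against 92.3 ± 33.7 CPM. The growth factor receptor gene EGFR was at 95.4 ± 12.3 against 199 ± 56.5 CPM. The groups did not overlap for any of these 5 genes, which were chosen after their values were seen.

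By edgeR, 0 of 24855 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.159, for PLXDC2. Unadjusted p was under 0.05 for 3649 genes (1978 higher and 1671 lower), where 1243 are expected by chance. That count depended on the controls used. It was 1236 without the 2 controls with the token 1M, 1998 with the 10K controls only and 4935 with the 1M controls only. DESeq2 called 338 genes (180 higher and 158 lower), among them PLXDC2 (adjusted p = 4.09e-08), TPBG (0.000155), CAMK2D (0.000305), ELAPOR1 (0.000334) and EGFR (0.00285), and limma voom called 0. In 1011 genes (4.07%) all OGDHL gRNA tumors lay on one side of all controls (590 higher and 421 lower), where chance gives 1.59%. Without control tumor 3, the only control with the token 100K, edgeR called 4 genes: MAST4 (2.18), DDC (2.80), GRIN2C (-3.20) and PLXDC2 (1.84), given as log2 fold changes and also named after their values were seen.

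The genes of glycolysis and of the response to low oxygen were lower together in the OGDHL gRNA tumors. Of 24 measured glycolysis genes 22 had a fold change below 0, with a mean log2 fold change of -0.62. By edgeR 13 fell when adjusted over the list alone (0 over all genes). Of 41 hypoxia response genes 37 had a fold change below 0, with a mean of -0.81, and over the list alone 26 fell and 1 rose (0 over all genes by edgeR). HK2, which carries out the first step of glycolysis, was at 24.2 ± 4.47 against 64.6 ± 29.2 CPM in controls (-1.42). The aldolase gene ALDOC was at 31.5 ± 6.61 against 66.0 ± 22.7 CPM (-1.07) and the enolase gene ENO1 at 551 ± 104 against 1040 ± 319 CPM (-0.92). NDRG1, induced by low oxygen and by androgen, was at 67.8 ± 21.3 against 434 ± 346 CPM (-2.68). Of the 4 hypoxia genes above 0, the carbonic anhydrase gene CA12 (1.48), chosen after its values were seen, was the one that rose over the list alone. Over all genes DESeq2 called HK2 (adjusted p = 0.0119), ALDOC (0.0167), ENO1 (0.0224), NDRG1 (0.00085) and CA12 (0.0169). All 4 OGDHL gRNA tumors had scores below the control mean in both lists. The lists share 7 measured members. Camera gave adjusted p = 3.50e-09 for glycolysis and 5.03e-13 for hypoxia, and both had adjusted p = 0.736 with an estimated correlation. Exact permutation p-values of the tumors' mean scores were 0.0159 and 0.0556, before adjustment over 46 lists (smallest adjusted exact p 0.32).

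Controls differed among themselves in these lists. Hypoxia scores were 0.26, 1.07, -0.41, 0.00 and 0.76 in control tumors 1 to 5 against -0.58 to -0.25 in the OGDHL gRNA tumors, so control tumor 3, the only control with the token 100K and the only one with the letters VB in its title, lay inside the OGDHL gRNA range. Within the token 100K the comparison rests on this lone control tumor, from which the mean difference was -0.01 for hypoxia and -0.19 for glycolysis. Here and below, list differences from control tumor 3 alone are differences in list score, not edgeR fold changes. In list score the differences from all controls were -0.75 for hypoxia and -0.60 for glycolysis.

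**Figure D2:**
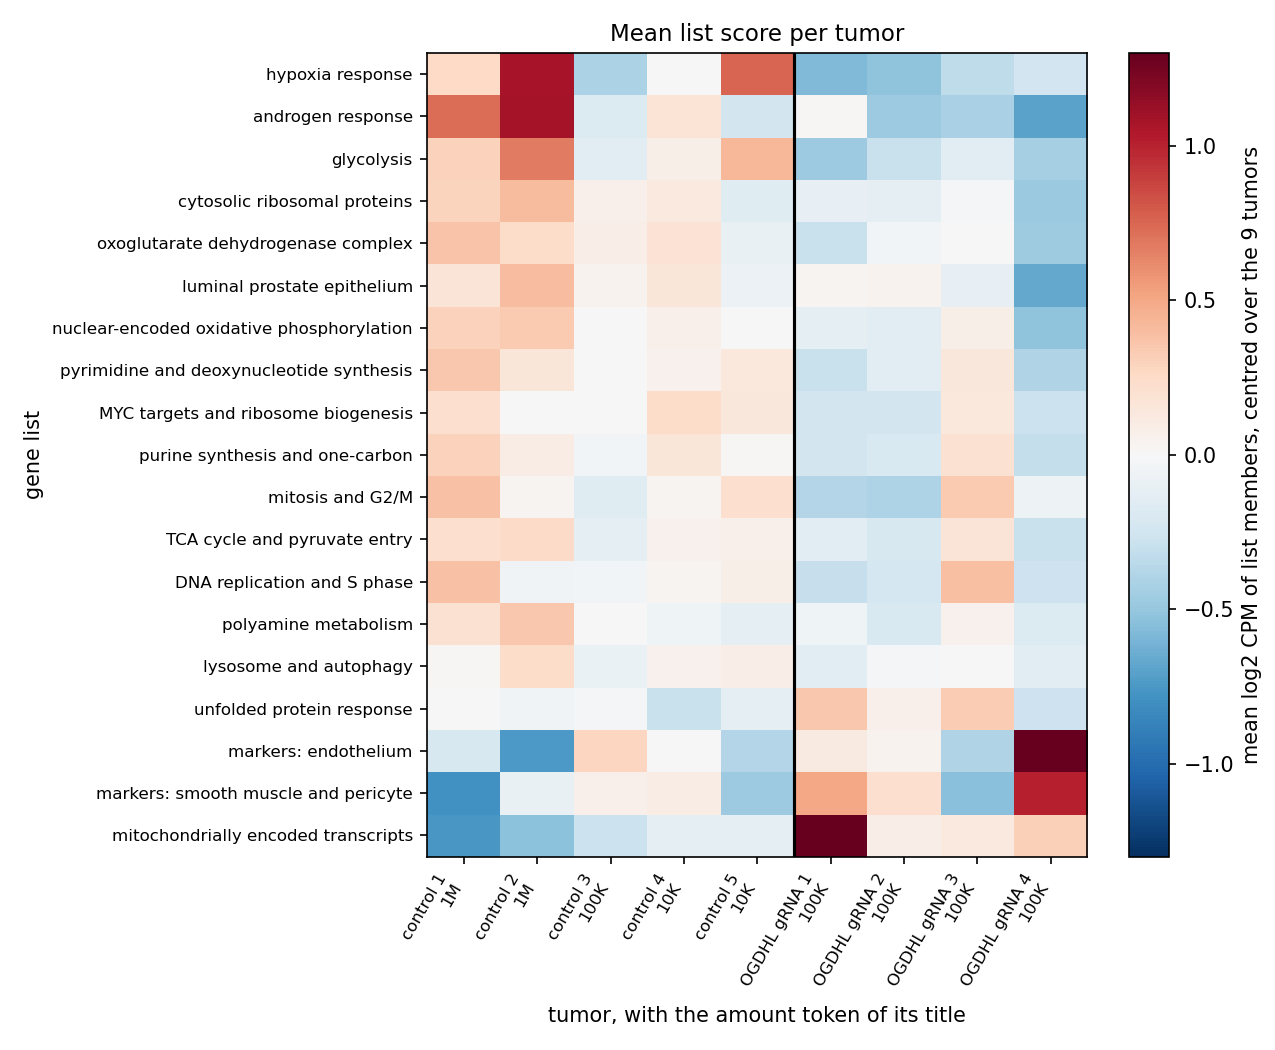
Mean list score (colour, mean centred log2 CPM) of the 19 lists past the camera threshold (rows) in each tumor (columns, with the amount token of its title); the black line parts 5 controls from 4 OGDHL gRNA tumors. Hypoxia and androgen response scores are highest in control tumor 2, and endothelial markers are highest in OGDHL gRNA tumor 4.

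Genes of the androgen response were also lower on balance. Of 64 measured members 55 had a fold change below 0, with a mean log2 fold change of -0.80. By edgeR 5 fell when adjusted over the list alone (0 over all genes). EAF2, an androgen-induced elongation factor gene, was at 2.30 ± 0.204 against 17.8 ± 15.7 CPM (-2.95), and the phosphatase gene PLPP1 was at 41.8 ± 8.89 against 75.9 ± 17.6 CPM (-0.86). DESeq2 called both over all genes (adjusted p = 0.000382 for EAF2 and 0.0201 for PLPP1). FKBP5, which encodes a chaperone of steroid receptors, was at 48.5 ± 7.52 against 220 ± 173 CPM (-2.18). Its exact permutation p was 0.0238 and its DESeq2 adjusted p over all genes was 0.00525. Its control values of 436 and 377 CPM came from the 2 tumors with the token 1M, while control tumor 3 had 57.1 CPM, below the 58.7 CPM of OGDHL gRNA tumor 3. KLK3, which encodes prostate-specific antigen (90.6 ± 74.1 against 88.0 ± 48.6 CPM, 0.04), had an edgeR adjusted p of 0.978. Its value rested on OGDHL gRNA tumor 1 (197 CPM), without which KLK3 was at -0.68, and it was 0.68 in OGDHL2930 and -1.13 in OGDHL2 tumors. Markers of luminal prostate epithelium were below 0 in 19 of 27 members (mean -0.33, camera adjusted p = 0.0382, and 0.784 with an estimated correlation). That mean rested largely on OGDHL gRNA tumor 4, with a score of -0.67. Tumors 1 to 3 scored 0.03, 0.05 and -0.10, and the controls -0.08 to 0.40. The luminal mean was -0.18 in OGDHL2930 (camera adjusted p = 0.512) and -0.55 in OGDHL2 tumors (0.00322). Camera gave adjusted p = 4.27e-09 for the androgen response and 0.736 with an estimated correlation. From control tumor 3 alone (score -0.18) the mean androgen difference in score was -0.22, against -0.71 from all controls. The exact permutation p of its scores, below the control mean in 4 of 4 OGDHL gRNA tumors, was 0.0714.

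Transcripts encoded in the mitochondrial genome were higher, while nuclear genes of oxidative phosphorylation were lower. Mitochondrially encoded genes took 9.95%, 12.04%, 14.6%, 13.9% and 14.9% of counts in control tumors 1 to 5 (13.1% ± 2.06) and 29.9%, 17.3%, 16.8% and 16.6% in OGDHL gRNA tumors 1 to 4 (20.1% ± 6.52). The exact two-sided permutation p, before any adjustment, was 0.00794, the smallest that 126 splits can give. Scores of the mitochondrially encoded list had the same exact p, which was 0.32 after adjustment over 46 lists. Without OGDHL gRNA tumor 1 the mean of that group was 16.9% and the exact permutation p was 0.0357. All 13 genes had a fold change above 0 (mean 0.90), and by edgeR 12 of them rose when adjusted over the list alone (0 over all genes). Among the 12 were MT-ND5 (8960 ± 2460 against 4920 ± 818 CPM, 0.86), MT-ND6 (0.89) and MT-ND4L (0.99). DESeq2 called these named genes over all genes (adjusted p = 0.0148, 0.0233 and 0.0469). Of 73 nuclear oxidative phosphorylation genes 72 had a fold change below 0, with a mean of -0.31, and 0 passed over the list alone. Examples are the complex I genes NDUFA8 (33.8 ± 5.2 against 47.1 ± 4.99 CPM, -0.48) and NDUFA10 (69.2 ± 7.00 against 91.3 ± 11.4 CPM, -0.40), both without overlap, and the ATP synthase gene ATP5MC3 (-0.40). Camera gave adjusted p = 1.42e-08 for the mitochondrially encoded list and 7.58e-14 for the nuclear list, and both had adjusted p = 0.736 with an estimated correlation. The exact permutation p of the nuclear list's scores, below the control mean in 4 of 4 OGDHL gRNA tumors, was 0.0556. Those scores were -0.12, -0.15, 0.08 and -0.53 in OGDHL gRNA tumors 1 to 4, so tumor 4 weighs most on the mean. Tumor 3 lay inside the control range (-0.0017 to 0.34). From control tumor 3 alone the mean differences in score were 0.73 for the mitochondrially encoded and -0.18 for the nuclear list. From all controls they were 0.815 and -0.323. Skeletal muscle markers, listed with the other host cells further on, were highest in OGDHL gRNA tumor 1, which also had the highest mitochondrial share.

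**Figure D3:**
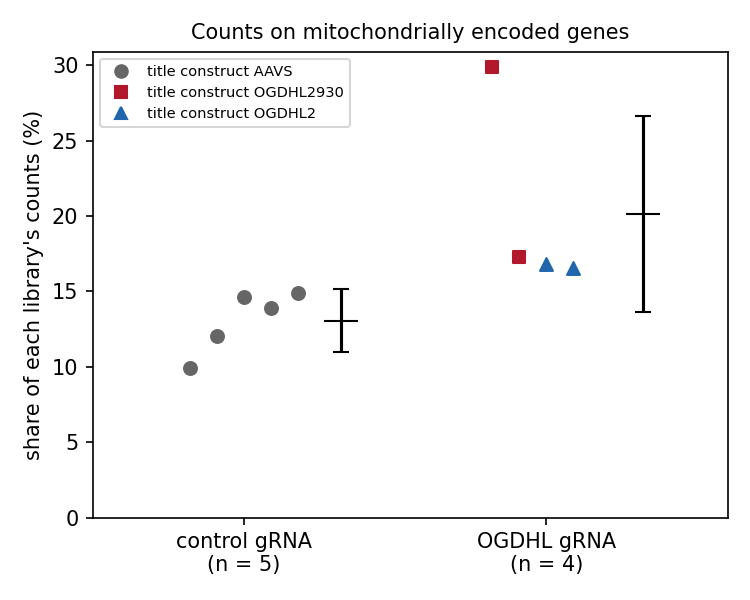
Share of each library's counts on mitochondrially encoded genes (y axis, percent, from 0) in each tumor (points, shaped by title construct), with the mean and SD of 5 control and 4 OGDHL gRNA tumors (bars). The OGDHL gRNA tumors lie between 16.6% and 29.9%, all above the controls.

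Genes of protein synthesis were lower by small amounts in nearly all members. Of 74 cytosolic ribosomal protein genes 72 had a fold change below 0 (mean -0.33), with RPS27A (-0.56), RPL24 (-0.48) and RPS10 (-0.40) leading. Many processed pseudogenes copy these genes, so reads could be shared with them. Of 50 MYC target and ribosome biogenesis genes 49 were below 0 (mean -0.27), led by the ribosome assembly factor UTP4 (-0.49), the prohibitin gene PHB1 (-0.39) and WDR74 (-0.44). By edgeR no member of either list passed over the list alone or over all genes. Of the members named here DESeq2 called RPS27A over all genes (adjusted p = 0.0334). Camera gave adjusted p = 3.64e-14 and 1.47e-09, and both had adjusted p = 0.736 with an estimated correlation. Exact permutation p-values of the scores were 0.0476 and 0.0397, though OGDHL gRNA tumor 3 (0.14) lay above the control mean of the MYC list (0.12). Control tumor 5 had a ribosomal score of -0.15, below those of OGDHL gRNA tumors 1 to 3 (-0.11, -0.13 and -0.03). Only OGDHL gRNA tumor 4 (-0.48) lay below every control in that list. From control tumor 3 alone the mean differences were -0.25 for the ribosomal and -0.15 for the MYC list.

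Nucleotide synthesis, cell cycle and TCA cycle genes were lower as well. In pyrimidine and deoxynucleotide synthesis 24 of 25 members had a fold change below 0 (mean -0.29), and 4 fell over the list alone, among them the nucleoside diphosphate kinase gene NME2 (207 ± 33.9 against 308 ± 37.0 CPM, -0.57), the uridine-cytidine kinase gene UCK1 (-0.54) and RRM2B (-0.80), which encodes a subunit of ribonucleotide reductase. Reads of NME2 may be shared with its close copy NME1. In the TCA cycle and pyruvate entry list 29 of 36 members were below 0 (mean -0.20), with SDHAF2 (-0.52), PDK1 (-0.99) and MDH1 (-0.59) first. Of these, PDK1 is also a member of the hypoxia response list. Mitosis genes were below 0 in 43 of 53 members (mean -0.21), with CDC20 (-0.50), CDC25B (-0.53) and MAD2L1 (-0.43) first, while the proliferation marker MKI67 was at 292 ± 94.4 against 275 ± 78.9 CPM (0.08). The mitosis mean was -0.51 in OGDHL2930 and 0.04 in OGDHL2 tumors. No member of the TCA cycle or mitosis lists passed over the list alone. Camera gave adjusted p = 8.95e-06, 6.07e-05 and 3.12e-05 for the pyrimidine, TCA cycle and mitosis lists, which were 0.736, 0.784 and 0.784 with an estimated correlation. Exact permutation p-values of their scores were 0.0556, 0.119 and 0.27. In each of these 3 lists 3 of 4 OGDHL gRNA tumors had a score below the control mean, with tumor 3 the exception. Control tumor 3 lay among the OGDHL gRNA tumors in TCA cycle (-0.13) and mitosis (-0.16) scores, so that the mean differences from this control alone were 0.01 and 0.03. Its pyrimidine score (-0.0098) also lay inside the OGDHL gRNA range of -0.394 to 0.146.

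A further 6 lists passed camera. Purine synthesis (mean -0.24), S phase (-0.16), lysosome (-0.15), polyamine metabolism (-0.15) and the oxoglutarate dehydrogenase complex (-0.33, 6 of 6 members below 0, OGDHL itself among them at -0.98) were lower, and the unfolded protein response (0.23) was higher, led by the chaperone gene HSP90B1 (0.80), chosen after its values were seen and the only member of that list past the threshold over the list alone. For these 6 lists camera adjusted p ran from 0.000729 to 0.0395, and with an estimated correlation their adjusted p were 0.736 or 0.784. Exact permutation p-values of their scores ran from 0.0397 to 0.357. Control tumor 3 lay among the OGDHL gRNA tumors in the purine (-0.03), S phase (-0.04), lysosome (-0.09), polyamine (0.003) and unfolded protein response (-0.02) scores. In the oxoglutarate dehydrogenase list it lay above all of them (0.09). In all, camera called 19 of 46 lists (15 lower and 4 higher), 0 held with an estimated correlation, and 0 passed with fry.

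Lineage markers of neuroendocrine prostate cancer did not pass as a list. The 29 measured members had a mean log2 fold change of 0.17 (19 above and 10 below 0), with a camera adjusted p of 0.416. The Notch ligand gene DLL3 was at 4.47 ± 1.27 against 6.16 ± 0.693 CPM (-0.46), HES6 at 3.95 ± 1.08 against 5.34 ± 1.75 CPM (-0.43) and the synaptic vesicle gene SYP at 3.57 ± 0.602 against 2.85 ± 0.656 CPM (0.32), with edgeR adjusted p of 0.368, 0.479 and 0.504. DLL3 was below the control mean in 4 of 4 OGDHL gRNA tumors, with an exact permutation p of 0.0317 before any adjustment. CHGA was not detected above the floor, at means of 0.0273 and 0.0249 CPM, and was not tested. The cell cycle inhibitor CDKN1A was at 49.1 ± 33.9 against 49.1 ± 17.1 CPM (edgeR adjusted p = 0.999), and its sign varied with the scaling.

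Markers of host cells, whose mouse reads may be counted on human genes, varied between tumors. Smooth muscle and pericyte markers were above 0 in 16 of 16 members (mean 0.65, camera adjusted p = 0.0128, and 0.784 with an estimated correlation), and RGS5 (1.31), chosen after its values were seen, passed over the list alone. Endothelial markers were above 0 in 18 of 21 members (mean 0.62, camera adjusted p = 0.0216, and 0.784 with an estimated correlation). Exact permutation p-values of the scores were 0.167 for smooth muscle and 0.254 for endothelium. The mean differences in score were 0.24 and -0.01 from control tumor 3 alone, against 0.54 and 0.48 from all controls. For smooth muscle OGDHL gRNA tumors 1 to 3 scored 0.50, 0.22 and -0.54, and the controls -0.78 to 0.09. For endothelium these OGDHL gRNA tumors scored 0.11, 0.04 and -0.39, inside the control range of -0.74 to 0.28. OGDHL gRNA tumor 4 had the highest score of both lists (1.01 and 1.29). It also held 1700 CPM of the collagen gene COL1A1, chosen after its values were seen, where the controls had a mean of 398 CPM, and its fibroblast (1.57) and myeloid (2.23) scores were the highest. Skeletal muscle scores were 3.39 and 1.65 in OGDHL gRNA tumors 1 and 2, 2.43 in control tumor 4 and below 0 in the other tumors. The muscle, fibroblast, myeloid, erythroid, adipocyte and keratinocyte lists did not pass camera (smallest p before adjustment 0.0612, for adipocytes). On log2(TPM + 1) camera called 26 lists (17 lower and 9 higher), 18 of them among the 19, and muscle, fibroblast, myeloid and adipocyte markers were among those called. Higher here means relative to the other genes. On this scale the called interferon (-0.06), mesenchymal (-0.10) and fibroblast (-0.04) lists counted as higher with mean differences below 0. That scale lowered the median of genes with a mean TPM of at least 1 by more (-0.32) than that of the other genes (-0.01), so calls on it depend on the level of a list's genes. Tumor 4 had the lowest mean correlation with the other tumors (0.937, against 0.964 to 0.972). Without it camera called 20 lists, of which 14 were among the 19.

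Tumors with the title names OGDHL2930 and OGDHL2 were set against each other to ask whether both showed the same differences. The labels do not say whether these names stand for different gRNAs. The interferon-stimulated list had scores of 0.48 and 0.67 in the OGDHL2930 tumors, -0.10 and -0.49 in the OGDHL2 tumors, and -0.18 to -0.02 in controls. Mitosis genes had scores of -0.38 and -0.41 in OGDHL2930 tumors and 0.34 and -0.07 in OGDHL2 tumors. OGDHL itself was at -0.53 in OGDHL2930 and -1.66 in OGDHL2 tumors, with an edgeR adjusted p of 0.854 for the difference. By edgeR 0 genes passed for OGDHL2930 against control, 0 for OGDHL2 against control and 0 between the constructs, with 2385, 3139 and 1245 genes at an unadjusted p under 0.05, while DESeq2 called 132, 165 and 49 and limma voom 0 in each. The smallest adjusted p for OGDHL2930 was 0.062, for LRRC7 (2.41), a gene chosen after its values were seen. The OGDHL2 count rested on 1 tumor, since without OGDHL gRNA tumor 3 edgeR called 2256 genes in tumor 4 against control.

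Log2 differences of both constructs from control correlated across 24855 genes, which are not independent replicates. Pearson's r was 0.456 and Spearman's rho 0.490, and 69.1% of genes had the same sign. This r was taken on differences of mean log2 CPM, and on edgeR's log2 fold changes it was 0.404. Both comparisons share the 5 control libraries. Simulated groups with no effect, in which genes varied independently of each other, gave a mean r of 0.281 (highest 0.297 of 50 simulations). The covariance was 0.160 against 0.0749 in the simulations, a difference of 0.0855. Genes of real tumors vary together, so these simulations cannot show whether the excess comes from an effect that the constructs share. With separate controls for each construct, the median r over 20 assignments was 0.246 (0.0870 to 0.428). Between the constructs, camera called 18 lists, of which 0 held with an estimated correlation. For interferon-stimulated genes the mean difference was 0.80 (camera adjusted p = 3.91e-11, and 0.173 with an estimated correlation), and for mitosis genes it was -0.55 (camera adjusted p = 8.50e-22, and 0.475 with an estimated correlation).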

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

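The tests of host cell RNA, of muscle RNA, of single tumors and of the title token were chosen after the results were seen. Those of depth, of transcript length and GC, and of other splits of the tumors were not. Among 198 groups of values searched (49 genes, 46 lists and 4 library measures in each genotype), 11 held a sample far from the others, and chance gives about 9.9, or 1 in 20 groups.

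The 9 tumors were also split in other ways into 5 and 4, and the counts of splits include the real one. Since edgeR called 0 genes, every split gives at least as many (100 of 100, highest other 3), which tests nothing. DESeq2 gave as many as the real 338 genes in 3 of 40 splits (highest other 907). At least 19 lists passed camera in 45 of 100 splits (highest other 29), and 9 of 126 splits had as many as 1011 genes without overlap (highest other 2233). Chance could be excluded for none of the last 3 counts. The split with 907 genes set control tumors 4 and 5 with OGDHL gRNA tumors 1 and 4 apart from the rest. It was picked as the highest after the counts were seen, and the median of the other splits by DESeq2 was 14. A split that does not follow genotype can thus give more calls than genotype does. What sets these tumors apart was not tested.

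OGDHL gRNA tumor 4 stood apart by its mean correlation with the other tumors (0.937). Its mean root mean square log2 difference from the others was 1.16, where the next largest was 0.878. Lower depth was argued against, since after thinning every library to the total of this tumor its distance was still 1.31 times the next largest, and so were trends with transcript length and GC, since without them the ratio was 1.3. RNA of host cells may account for it: the tumor had the highest score in 7 of 8 host cell lists, with 1700 CPM of COL1A1 (median of the others 269), 51.1 CPM of LYZ (4.72) and 37.6 CPM of HBA1 (2.88). Not every marker followed: EGFL7 (17.9 CPM, median of the others 28.1), NOTCH3 (44.2, 55.4) and KRT10 (18.3, 23.8) were among those lower in tumor 4. These single markers were chosen after their values were seen. Control tumor 2 had 18.9 CPM of HBA1 and an erythroid score of 2.46, against 2.63 in OGDHL gRNA tumor 4. Whether the marker reads of tumor 4 came from mouse cells stays open, as does another difference in the make-up of this single tumor. OGDHL gRNA tumor 3, which shares the construct of tumor 4, had low scores for fibroblasts (-0.90) and adipocytes (-0.55). A single other tumor cannot decide whether the construct plays a part.

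The mitochondrial share of 29.9% in OGDHL gRNA tumor 1 was far from the rest of its group. That tumor alone does not account for the difference, since the other 3 OGDHL gRNA tumors also lay above every control, but without it their mean was 16.9% in place of 20.1% (exact permutation p = 0.0357). Muscle RNA was argued against as the whole cause: the log2 difference in share was 0.591 (SE 0.219) without and 0.504 (SE 0.188) with the muscle score as a covariate, and OGDHL gRNA tumor 3, with the lowest muscle score (-2.01), had 16.8%. The title token cannot be told apart from genotype, as the only control with the token 100K (14.6%) is a single tumor, which also differs from the other controls in its title letters. RNA quality was not tested, and an effect of OGDHL loss stays among the open explanations.

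The 15 lists lower in OGDHL gRNA tumors were weighed against the controls used. With the 10K controls as the only controls 11 of the 15 stayed past the camera threshold, too few to argue against a part of the 2 controls with the token 1M and too many to hold them responsible. Trends with transcript length and GC were argued against as the whole cause, as 13 of 15 stayed past the threshold without them. For the token 100K, the 1 control that carries it lay above every OGDHL gRNA tumor in 3 of the 15 lists, and genotype and token cannot be told apart with a single such control. As many lists were called in 45 of 100 splits, the real one included, so no biological reading of them is offered.

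Other single values far from their group were low DLST in control tumor 5 (52.9 CPM), low DLD in control tumor 3 (150 CPM), high NDRG1 in OGDHL gRNA tumor 4 (99.7 CPM) and high PMPCA, a gene chosen after its values were seen, in OGDHL gRNA tumor 2 (69.8 CPM). Among list scores these were high S phase (0.39) and MYC target (0.14) scores in OGDHL gRNA tumor 3, a low heat shock score in OGDHL gRNA tumor 2 (-0.27), a high WNT score in control tumor 3 (0.13) and a high skeletal muscle score in control tumor 4 (2.43).

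By camera with the preset correlation 18 lists differed between OGDHL2930 and OGDHL2 tumors, and 0 did with an estimated correlation (adjusted p of 0.173 or above). Mean log2 differences, OGDHL2930 minus OGDHL2, were above 0 for skeletal muscle markers (4.37), interferon-stimulated genes (0.80), mitochondrially encoded transcripts (0.59), the NOTCH pathway (0.38), luminal epithelium (0.37) and MHC class I antigen presentation (0.28). They were below 0 for mesenchymal genes (-1.07), fibroblast markers (-1.02), endothelial markers (-0.66), the integrated stress response (-0.65), the NRF2 response (-0.62), mitosis (-0.55), S phase (-0.37), hypoxia (-0.34), p53 targets (-0.27), DNA damage response (-0.22), purine synthesis (-0.19) and MYC targets (-0.18). Each construct had 2 tumors, and tumor 4 weighs on the lists of host cell types.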

How the results depend on the processing

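The alternatives that left out mitochondrial genes or the 1M controls, limited the list test to 1M or 10K controls, or permuted list scores were chosen after seeing the data. The log2 fold change of OGDHL stayed below 0 and short of the threshold in all alternatives run (-1.44 to -0.64, adjusted p 0.0939 to 1). The count of 0 genes between genotypes held under all but 4 alternatives: DESeq2 338, 1M controls only 7, 10K controls only 2 (GATA3 and GRIN2C, like the other genes here named after their values were seen), and leaving out single tumors 0 to 4 (4 without control tumor 3). For OGDHL2930 the count was 2 (LRRC7 and CERK) with no filter and 2 with the strict filter, 132 with DESeq2 and 0 to 2 leaving out single tumors. For OGDHL2 it was 165 with DESeq2 and 0 to 2256, the latter without OGDHL gRNA tumor 3. Between constructs it was 49 with DESeq2 and 0 to 27, again without tumor 3. Where an arm kept 1 tumor, that lone tumor is assumed to vary like the others. Of the 19 lists called, 0 passed with an estimated correlation, 0 with fry, 0 by exact permutation and 5 (glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded, MYC and ribosomal) with the token as a covariate, which sets control tumor 3 alone against the OGDHL gRNA tumors and by which mitosis (0.0284) and endothelial markers (-0.0149) reversed and the means of the TCA cycle (0.0105) and lysosome (0.0129) lists changed sign; leaving out single tumors gave 14 to 29 lists (29 without OGDHL gRNA tumor 3). The median correlation of the constructs was 0.246 with split controls, against 0.456 with shared ones. Shared controls alone raise r, to a mean of 0.281 in simulations with no effect, and split controls also leave fewer controls per construct. How much each adds to the fall was not tested. Of 830 values of named genes, those without single tumors not counted, 28 changed sign, none of them past the threshold and part of them on the TPM scale, which lowers most genes. The constructs' correlation over genes called by edgeR could not be given, since none passed, and over DESeq2's calls it was not computed. No paired analysis was possible because replicate numbers only name the tumors. At this depth 3 counts are at most 0.0553 CPM, and CHGA, below that on average, was not tested.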

Other observations

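The single genes given here were chosen after their values were seen. These lists did not pass camera between the genotypes on TMM-scaled counts, and are given as mean log2 fold changes of OGDHL gRNA minus control. WNT pathway genes had a mean of 0.28. By edgeR's test the transcription factor gene LEF1 (1.26) passed over the list alone (adjusted p = 0.0158) but not over all genes (0.296). DESeq2 called LEF1 over all genes (adjusted p = 0.00504). Among oxoglutarate-dependent dioxygenases (mean -0.19) the lysyl hydroxylase gene PLOD2 (-2.60) and the histone demethylase gene KDM4B (-0.67) fell and TET2 (0.62), which oxidizes methylcytosine, rose over the list alone. Cholesterol synthesis (-0.02) and fatty acid oxidation (-0.08) had means near 0. The integrated stress response had a mean of 0.03, with -0.35 in OGDHL2930 tumors (camera adjusted p = 0.00238) and 0.31 in OGDHL2 tumors (0.0045). The difference between the constructs had adjusted p = 0.609 with an estimated correlation. On log2(TPM + 1), a scale whose shift depends on the level of a gene, dioxygenases (camera adjusted p = 0.0159) and fatty acid oxidation (0.0495) passed.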
